A study of Homo sapiens with 8 samples.

How the data were processed

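Chromatin loops were measured by in situ Hi-C in C-28/I2 cells, an immortalised human chondrocyte line, in 4 technical replicates that the authors merged into 1 map and 1 loop list. Active chromatin was measured by CUT&RUN for H3K27ac, the acetylation of lysine 27 of histone H3 that marks active promoters and enhancers. The CUT&RUN libraries came from primary articular chondrocytes of 2 donors kept in the control vehicle, with 1 library per donor at each of 2 nominal times. Loops and H3K27ac therefore come from different cells.

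The submitters' processing notes name BWA 0.7.17, Juicer 1.14.08, Trim Galore 0.4.3, SAMtools 1.9, MACS2, bedtools 2.26, deepTools 3.0.1 and genome build hg19, with no role or order. Per the file headers, loops came from SIP, with a call at finer resolution and anchors deposited at 20 kb. The deposited loop score and pixel value are the loop caller's own, and the score was used only to rank, filter or describe loops within the list. The deposited probability of enrichment is a fraction, and its lowest value was 0.900. Peak lists were deposited per library, and the authors also deposited 1 merged list per time, tied to the libraries of a title time by the labels' description. The names of all these peak lists mention ATAC, another assay, whereas the labels describe CUT&RUN with an antibody to H3K27ac. The lists were taken as H3K27ac on the word of the labels, and the peaks alone do not settle which is right. Each peak carries a deposited fold enrichment, a ratio of signal over the caller's background. Each peak also carries −log10 p and −log10 q as the authors deposited them, and these were used only to rank, filter or describe peaks within a list. The lowest −log10 q was 2.01. Read depth behind the peaks is unknown, since the peak lists hold no read counts, and no antibody control was used here.

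Libraries were grouped by the time in their titles (90 and 180). The treatment field of the labels gives another time for 2 of the 4 libraries, which would make time and donor the same split. That grouping was run as an alternative. The donor number is shared between the times, so same-numbered libraries come from the same donor, and within-donor ratios were computed beside the unpaired comparison. Only the 22 autosomes were used. Coordinates are hg19 and counted from 1.

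Peaks of the 4 libraries were merged into regions where they overlapped by at least 1 bp, and a library held a region when 1 of its peaks overlapped it. Regions held by all 4 libraries are called shared. Base overlap between libraries was the Jaccard index, the bases covered in both divided by the bases covered in either. With 4 libraries there are 3 ways to form 2 pairs (by time, by donor and crossed), and an exact permutation test of 2 against 2 libraries cannot give a p under 0.3333. Shared regions lying within 12500 bp of each other were joined into domains.

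The chance level of H3K27ac at anchors came from moved loops. Each loop was moved as a whole to a random place on its own chromosome, with its span kept, among the 2729 bins of 1 Mb that held a peak. A set of 1000 draws gave the mean, the SD and a one-sided permutation p, of which 0.001 is the smallest. The 95% range of a fold is the observed share divided by the bounds of the central 95% of the draws. Differences of medians between loop classes were tested with a two-sided permutation test of 100000 resamples, with bootstrap intervals from 2000 resamples. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. All tests over loops, anchors or regions treat items of 1 pooled map as independent, and such items are not replicates.

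The statistics were tested on simulated data. With H3K27ac regions scattered at random, 20 simulations over 9076 loops gave a mean fold of 0.999 ± 0.0129 (SD), and 2 of the 20 had a permutation p under 0.05. With regions planted in 30% of anchors, the fold was 1.51 ± 0.00964 and all 20 passed. The scattered regions lacked the clustering of the real ones, so the chance level was not checked for clustered regions. Of 1500 regions planted per time, 99.4% were recovered on average. The simulated libraries were copies of the shared regions with small shifts in position. High recovery was therefore built in, and the rate of false time regions was not measured. For the loop score, a planted shift of −0.12 in the median was estimated as −0.118 and found in 100 of 100 simulations, against 3 of 100 without a shift (permutation test).

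Alternatives were stricter peak thresholds (−log10 q of at least 5 or 10), equal numbers of peaks per library, peaks joined within 1 kb, a local shift of loops by 500 kb to 2 Mb, the higher-scoring part of the loops, the merged peak lists, anchors widened by 10 kb, the treatment-field grouping, the donor pairing, and each library left out in turn. Added after the data were seen were a stricter overlap rule, the joint moving of all loops of a chromosome, the pixel value, and the comparison of scores within 10 classes of loop span. Figures by span class, the tests of the highest-scoring loops, the side test over 200 kb and the comparison of moved loops with their own product were also added then. A pair of tests on why peak numbers moved in opposite directions in the donors was run and is not weighed here; their values are given without an explanation.

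Regions were named by rules set before the data were examined: the 10 anchors with the most loops to other anchors with H3K27ac, the 15 domains with the most covered bases, and per time the 10 regions ranked by the lower −log10 q of the 2 libraries; the text names the leading ones. The rules were written for genes. The gene table used here is of assembly GRCh38.p14 and the peaks and loops are in hg19, so no gene was placed or named, and the planned promoter comparisons and the 19 fixed gene lists (364 genes) were not run. The loops and other items that the text singles out beyond these rules were chosen after their values were seen. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.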

Results

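Loops and active chromatin were mapped in human chondrocytes, the cells of cartilage, in a study of genes that may carry risk for osteoarthritis. The loop list held 9271 loops called on 1 pooled Hi-C map of C-28/I2 cells, of which 9076 were on autosomes. H3K27ac peak lists came from primary articular chondrocytes of 2 donors at nominal times of 90 and 180 min in vehicle. At 90 min the libraries had 105354 and 101961 autosomal peaks (donors 1 and 2), and at 180 min they had 94056 and 106243. The peaks covered 57.7 to 61.9 Mb per library. Median peak width was 319 and 315 bp at 90 min and 429 and 336 bp at 180 min. The shortest peak in each library was 200 bp, and 30.7% to 38.6% of the peaks of a library had exactly that width.

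Shared regions held most of the bases covered by a peak in any of the 4 libraries. Of 122920 merged H3K27ac regions, 69383 (56.4%) were called in all 4 libraries, and these held 63.2 Mb, or 77.8% of the covered bases. A shared region counts bases covered in any library, so fewer bases were covered in all 4 at once. Where the peaks of each library had to cover at least 50% of a region, 59070 regions (48.1%) were shared. As merged, shared regions were wide, with a median of 898 bp, whereas regions called in 3 libraries had a median of 200 bp. Regions called in 1 library numbered 21537 (17.5%). The median of the strongest −log10 q in a shared region was 18.6. With peaks of −log10 q of at least 10 only, the shared regions fell to 31449 of 69422 (45.3%), and with −log10 q of at least 5 they were 52946 of 106266 (49.8%).

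Neighbouring shared regions were joined into domains, which were ranked by their covered bases. The domain with the most covered bases lay on chromosome 16 from 69832564 to 69969347 and held 28 regions that covered 31.5 kb. It ranked between 1 and 5 in each of the 4 libraries on its own. The next was also on chromosome 16, from 17383484 to 17511466, with 29.3 kb in 26 regions and no loop anchor. Chromosome 11 from 128268815 to 128403040 followed with 28.6 kb in 21 regions. A domain on chromosome 3 from 50223876 to 50397137 held 28.3 kb in 33 regions and touched 1 anchor. The domain on chromosome 6 from 2086486 to 2204429 held 26.3 kb in 20 regions and touched 3 anchors that took part in 6 loops, the most loops among the 15 leading domains. On chromosome 14, a domain from 61958398 to 62055467 held 24.7 kb and touched 3 anchors. The domain on chromosome 6 from 39136725 to 39316501 was the longest of the 15, at 180 kb, and held 24.7 kb in 27 regions. The last of the 15, on chromosome 5 from 77780961 to 77918082, held 23.2 kb but ranked 296 in 1 library when that library was joined on its own. In all, the shared regions formed 34953 domains, and the 500 with the most covered bases (1.43%) held 9.81% of the bases.

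The time comparison asked whether H3K27ac differed between 90 and 180 min in vehicle. The mean number of peaks was 103658 ± 2399 (SD, n = 2) at 90 min and 100150 ± 8618 (SD, n = 2) at 180 min, a log2 ratio of −0.0497. That difference lay within the spread at 180 min but exceeded the SD at 90 min (two-sided exact permutation p 1). Covered bases were 58.8 ± 1.53 Mb (SD, n = 2) at 90 min and 61.4 ± 0.806 Mb (SD, n = 2) at 180 min. Both donors covered more bases at 180 min, with log2 ratios of 0.0218 and 0.102 and an exact permutation p of 0.3333, the smallest that 2 against 2 libraries can give. The sign for peak numbers rested on the library of donor 1 at 180 min, without which the log2 ratio was 0.0355.

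Libraries resembled each other more by donor than by time. The Jaccard index of covered bases was 0.704 and 0.726 between the times of a donor, 0.685 and 0.670 between donors at the same time, and 0.688 and 0.661 between libraries that differed in both. Regions called in both libraries of 180 min and in neither of 90 min numbered 1568, and 1659 showed the opposite. Which direction was larger depended on the settings. It turned to 1989 against 1556 with equal numbers of peaks and to 2315 against 1931 where peaks had to cover at least 50% of a region. Without the 180 min library of donor 1 it was 8723 against 3671, and without that of donor 2 it was 7132 against 11178. In these 2 settings only 1 library has to meet the criterion at 180 min, so the directions are not counted by the same rule. The time split thus gave 3227 regions, against 7524 for the donor split and 3688 for the crossed split. With only 3 splits of 4 libraries, no share under 0.3333 is possible. With the times of the treatment field, 2 libraries change places and the time split becomes the donor split, with 4423 regions at 180 min only and 3101 at 90 min only. When peaks within 1 kb were joined, the title times gave 969 regions of 180 min only and 775 of 90 min only.

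**Figure D1:**
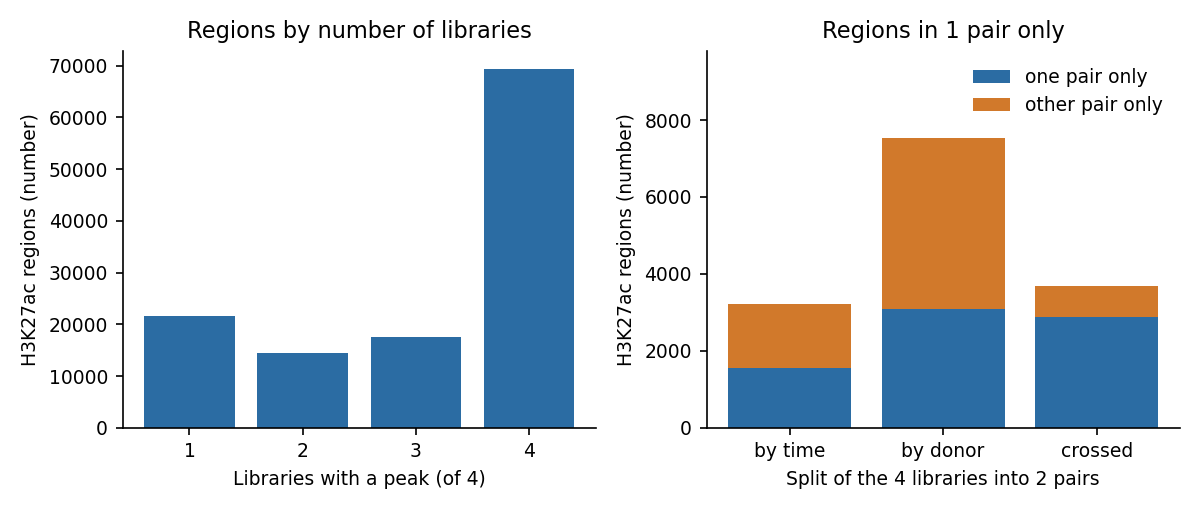
Left, bars give the number of merged H3K27ac regions by the number of libraries with a peak, and 69383 of the regions lie in all 4. Right, bars give the regions called in both libraries of a pair and neither of the other for the 3 splits, with 180 min (blue) and 90 min (orange) for the split by time, donors 1 and 2 in that order for the split by donor, and the mixed pairs for the crossed split; the donor split is the tallest at 7524.

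The median strongest −log10 q was 6.34 in regions of 180 min only and 6.01 in regions of 90 min only. Over both directions it was 6.29, close to the 6.34 of the crossed split and below the 7.16 of the donor split, whose regions were likewise called in 2 libraries. The leading region of 180 min only lay on chromosome 9 from 69963383 to 69963917, with −log10 q of 15.5 and 21.7 in the 2 libraries. It was followed by chromosome 13 from 37573100 to 37573312 (12.2 in the weaker library) and chromosome 19 from 27890268 to 27890642 (12.1). On chromosome 11, a region from 65262098 to 65262412 had 11.7 in the weaker library. The leading region of 90 min only was on chromosome 1 from 61548161 to 61548360, with 14.1 and 15.5. A region on chromosome 6 from 39183121 to 39183689 reached 12.01 in the weaker library and lay inside the chromosome 6 domain that starts at 39136725. The regions on chromosome 17 from 43507050 to 43507326 and on chromosome 19 from 8608978 to 8609177 both had 11.7. Of the 10 leading regions of 90 min only, 6 were 200 bp wide, the shortest width called. Over all regions of 90 min only the median width was also 200 bp, against 401 bp for 180 min only. The strongest −log10 q was under 5 in 33.0% of regions of 90 min only and in 22.9% of those of 180 min only. The merged lists of the authors held 118379 peaks at 90 min and 115890 at 180 min, and 90.8% and 91.1% of them overlapped the other list. Peaks present only in the merged 90 min list were found in 38.1% and 32.9% of cases in the libraries titled 90 min and in 2.71% and 10.2% in those titled 180 min. For the merged 180 min list the shares were 31.2% and 36.7% in the libraries titled 180 min and 5.09% and 3.32% in the others. The merged lists thus followed the times of the titles.

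Loops in C-28/I2 cells had a median span of 260 kb (quartiles 140 and 480 kb, range 40 to 7800 kb). Loops over 1 Mb numbered 358 (3.94%), and 1056 (11.6%) spanned under 100 kb. The 9076 loops joined 14038 different anchors, of which 10800 took part in 1 loop, 2540 in 2 and 698 in 3 or more. The median loop score was 2.89 (quartiles 2.46 and 3.47). There is no replicate check on the loops, since the technical replicates were pooled.

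The central comparison set loop anchors of the cell line against active chromatin of primary chondrocytes. Anchors held H3K27ac more often than moved loops did. Of anchor ends, 51.4% overlapped a shared H3K27ac region, against 32.7% ± 0.371 (SD of 1000 draws) for moved loops, a fold of 1.57 (95% range 1.53 to 1.60). Loops with H3K27ac at both anchors made up 30.98% against 14.2% ± 0.378, a fold of 2.18 (2.08 to 2.30). In both cases the one-sided permutation p was 0.001, the smallest possible. After local shifts the folds were 1.404 and 1.87. The share with both anchors was 1.17 times the 26.4% that the shares of the single anchors would give. Moved loops exceeded their own product of 10.7% by 1.33-fold, and locally shifted loops exceeded theirs of 13.4% by 1.24-fold. Such a ratio has less room to rise where single anchors hold H3K27ac more often, as in the called loops. It therefore does not decide whether called loops pair active anchors more than moved loops do.

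Around the anchors of the 2598 loops of at least 440 kb, H3K27ac peaked at the anchor itself. Pooled over these loops, shared regions covered 3.22% of the anchor bases (± 0.150, SEM over 22 autosomes). The 20 kb windows up to 200 kb away had between 2.37% and 2.75%. The adjoining window had 2.60% ± 0.117 inside the loop and 2.71% ± 0.142 outside it.

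**Figure D2:**
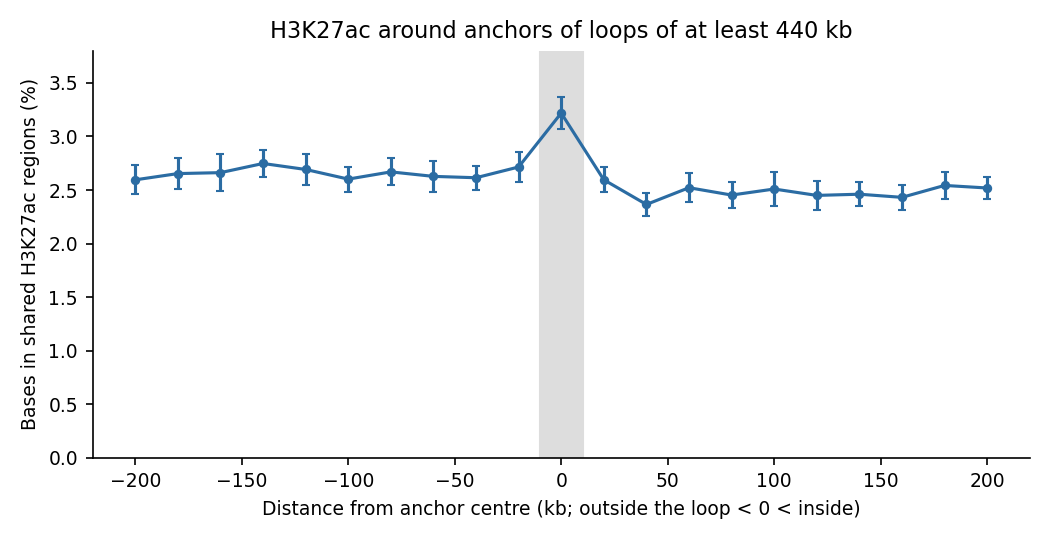
The line gives the mean percentage of bases in shared H3K27ac regions (y axis), pooled over loops of at least 440 kb. The x axis is the distance in kb from the anchor centre in 20 kb windows, negative outside the loop. Error bars are the SEM over 22 autosomes and the grey band is the anchor. The anchor stands at 3.22% above flanks of 2.37% to 2.75%.

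Short loops joined active chromatin most often. Among loops of 40 to 80 kb, 48.7% had H3K27ac at both anchors, against 17.6% ± 1.12 (SD of draws) when moved, a fold of 2.77 (2.44 to 3.13). The share was 31.9% at 240 to 260 kb, with a fold of 2.25 (1.88 to 2.73). For loops from 760 kb upward it was 18.6% against 11.8% ± 1.11, a fold of 1.57 (1.33 to 1.92). With local shifts the fold was 2.13 (1.93 to 2.37) in the shortest class and 1.61 (1.35 to 1.94) in the longest.

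**Figure D3:**
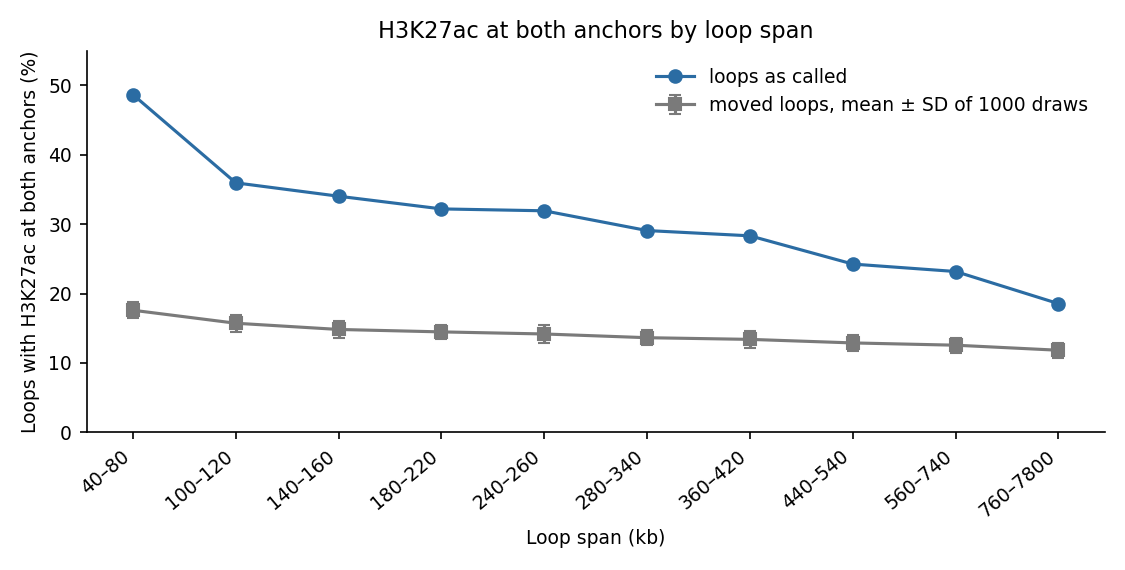
Points give the percentage of loops with H3K27ac at both anchors (y axis) in 10 classes of loop span in kb (x axis), for loops as called (blue) and for moved loops (grey, mean ± SD of 1000 draws). The called loops lie above the moved ones in each class, from 48.7% against 17.6% in the shortest to 18.6% against 11.8% in the longest.

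Loops with H3K27ac at both anchors were shorter and had lower scores than loops with none. There were 2812 loops with H3K27ac at both anchors (30.98%, exact interval 30.0% to 31.9%), 3702 with it at 1 anchor (40.8%) and 2562 with none (28.2%). Median span was 220, 280 and 320 kb in that order, and the difference between both and none was −100 kb (bootstrap interval −140 to −100). Median score was 2.82, 2.91 and 2.94, and the difference between both and none was −0.122 (−0.170 to −0.0721). Each of these differences had a permutation p of 1e-05, the smallest that 100000 resamples can give. Within 10 classes of loop span the score difference turned to 0.0409 (permutation p 0.112), so the lower score was not seen at equal span. With the merged peak lists the difference over all spans shrank to −0.0678 and −0.0706 (permutation p 0.00861 and 0.00726). With the pixel value in place of the score the difference was −0.0849 (permutation p 0.0570). The pixel value is another measure, so the size of that difference cannot be set beside those of the score.

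Some active anchors joined several others. Of the anchors with H3K27ac, 4717 were looped to at least 1 other such anchor, 106 to at least 3 and 6 to at least 5. No chance level was computed for these counts, and 50.2% of all anchors held H3K27ac. The leading anchor, on chromosome 6 from 139680001 to 139700000, had 7 loops, of which 6 ran to anchors with H3K27ac at distances of 400 to 2200 kb. It held 1131 bp of H3K27ac. Of all 7 loops, 6 pointed to higher coordinates, including the loop to the anchor without H3K27ac. The strongest of the 7 (score 5.19) ended at 140760001 to 140780000. The anchor on chromosome 2 from 47100001 to 47120000 had 5 loops, all to anchors with H3K27ac, at 180 to 880 kb. On chromosome 10, the anchors from 3820001 to 3840000 and from 4800001 to 4820000 each had 5 such loops and stood 980 kb apart. The farthest partner of the first lay at that same distance and both had a top score of 4.08, so they appear to share a loop. The anchor on chromosome 21 from 36760001 to 36780000 had 5 such loops at 340 to 640 kb, and that on chromosome 10 from 77160001 to 77180000 had 5 of its 6 loops to active anchors. Among those of the 10 leading anchors with 4 such loops, chromosome 14 from 75760001 to 75780000 held the most H3K27ac, at 4508 bp. The anchor on chromosome 9 from 137020001 to 137040000 had the strongest loop of the 10 leading anchors, with a score of 8.90.

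**Figure D4:**
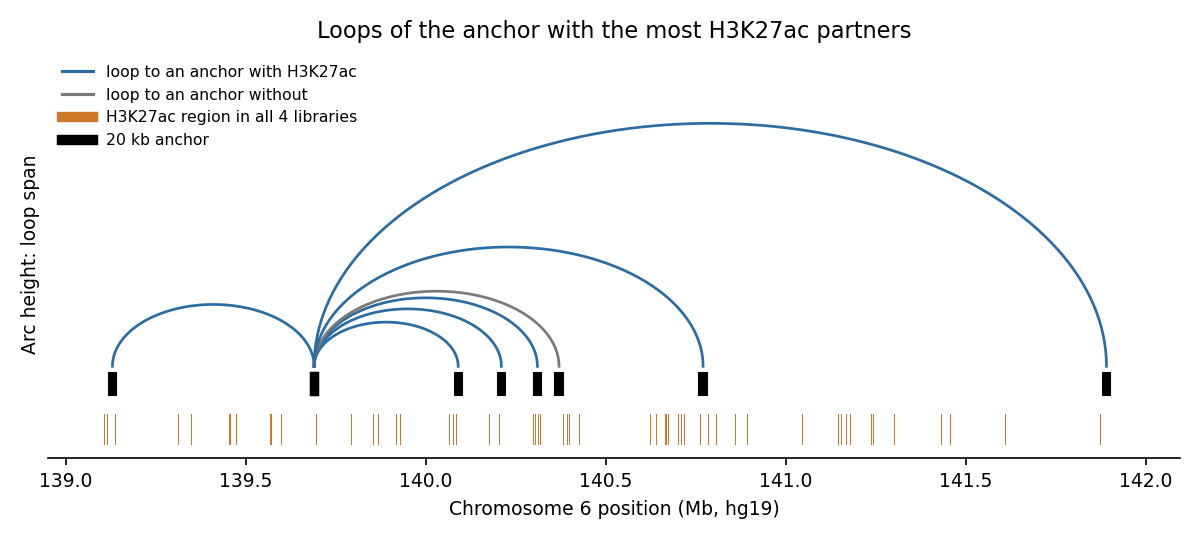
Arcs are the 7 loops of the chromosome 6 anchor from 139680001 to 139700000 along the chromosome in Mb (x axis, hg19), with height proportional to span; blue arcs run to anchors with H3K27ac, the grey arc to one without. Black boxes are 20 kb anchors and orange bars are H3K27ac regions shared by the 4 libraries, with narrow ones widened so that they can be seen; 6 of the 7 partners hold H3K27ac.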

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

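The tests of the highest-scoring loops, the joint moving of the loops of a chromosome and the values behind the donors' opposite peak numbers were chosen after the data were seen; the other tests were planned. The number of H3K27ac peaks moved in opposite directions in the donors, with log2 ratios of 180 over 90 min of −0.164 in donor 1 and 0.0594 in donor 2. The difference of −0.223 was not tested, since each donor has 1 library per time. It was −0.140 after peaks within 1 kb were joined and −0.391 over peaks of −log10 q of at least 10, whereas covered bases rose in both donors and differed by −0.0800.

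H3K27ac at loop anchors exceeded that of moved loops 1.57-fold. Loops could simply lie in stretches rich in H3K27ac. Local shifts of 500 kb to 2 Mb raised the moved share from 32.7% to 36.6%, yet the fold was still 1.404 (1.38 to 1.43). Such shifts cannot address rich stretches around anchors that are shorter than 500 kb. Weak peaks were not needed for the excess. Over peaks of −log10 q of at least 10, 32.8% of anchor ends held H3K27ac against 19.0% for moved loops, a fold of 1.73. A fold has more room to rise where the moved share is lower, so its larger size does not show a stronger excess. Clustering of loops did not carry the excess: with all loops of a chromosome moved together, the highest share in 1000 draws was 34.5%, against 51.4% observed. The hypothesis that loops of chondrocytes tend to be anchored in active chromatin stays open, as does shared preference of both measurements for open or readily mapped sequence, which was not tested.

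The regions called at 1 title time may reflect library differences that do not follow time. The time split gave 3227 regions, fewer than the donor split (7524) and the crossed split (3688); with equal numbers of peaks the values were 3545, 7663 and 3340. Weak calls near the threshold are a candidate explanation, but the median strongest −log10 q of 6.29 fell between the bounds set for deciding (5 and 10). A response to time in vehicle stays untested, because 3 splits cannot separate it from chance and because the labels disagree on the times.

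More of the highest-scoring loops had no H3K27ac in primary chondrocytes. The strongest joined chromosome 5 from 175340001 to 175360000 with 177560001 to 177580000 (score 38.1), with no H3K27ac at either anchor. The next joined chromosome 11 from 116520001 to 116540000 with 120620001 to 120640000 (score 37.1). Its anchors held only 400 and 200 bp, yet it counted as a loop with H3K27ac at both anchors. Shared regions of at most 250 bp had a fold of 1.01 at anchors with local shifts. Such small amounts may therefore be background, which was not tested. Among the 50 highest, 46.0% (exact interval 31.8% to 60.7%) had no H3K27ac at either anchor. Of the others, 28.1% had none (Fisher's exact p 0.00712, adjusted 0.00949 over 4 tests). Among other loops in the same span classes the share was 32.8%, just inside that interval. The longest class ran from 760 to 7800 kb, so loops over 2 Mb were compared mostly with shorter ones. Some of the 50 lie at the same place. Loops on chromosome 17 from 21520001 and from 21220001 both ended at 21680001 to 21700000. Fisher's exact test and the interval count such loops as independent. H3K27ac at both anchors did not differ detectably (26.0% against 31.01%, Fisher's exact p 0.540, adjusted 0.540). Chromosome stretches rearranged in the cell line could give long spans, and 16.0% of the 50 spanned over 2 Mb against 0.255% of the others (Fisher's exact p 3.38e-12, adjusted 1.35e-11). The score also rose with span, however. In loops with no H3K27ac its median was 2.28 at 40 to 80 kb and 3.37 from 760 kb upward. Long span therefore does not show rearrangement, and whether the long loops were those without H3K27ac was not tested. Of the 50, 10.0% lay within 1 Mb of a bin with no peak against 0.454% (Fisher's exact p 4.78e-06, adjusted 9.56e-06), but such bins are defined by the lack of H3K27ac, so this decides nothing. Most of the 50 spanned under 2 Mb, no biological explanation was tested, and these tests do not tell the explanations apart.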

How the results depend on the processing

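Over 82 alternatives, 64 kept the direction and side of the threshold, or stayed within the spread or 1.5 times the count. The folds of H3K27ac at single anchors (1.404 to 1.73) and at both anchors (1.79 to 2.75) kept their direction and a permutation p at its smallest value in all 11 alternatives each. The span difference lay between −140 and −100 kb in its 8 alternatives, and the Jaccard index stayed lower for the same time than for the same donor (by −0.0470 to −0.0390) in its 4. The log2 ratio of peak numbers turned to 0.00113 with −log10 q of at least 10 and to 0.0623 with the treatment-field times, and ranged from −0.140 to 0.0355 with a library left out, positive only without the 180 min library of donor 1. With the donor as a block it was −0.0522 (exact sign-flip p 1, smallest possible 0.5), and the block changed no call. Shared regions fell to 31449 with −log10 q of at least 10, since fewer peaks enter. Regions of 180 min only and 90 min only came to 969 and 775 with peaks joined within 1 kb and to 4423 and 3101 with the treatment-field times, and ranged from 4379 to 8723 and from 3671 to 11178 with a library left out, with the larger direction turning only without the 180 min library of donor 1, when 1 library fewer has to meet the criterion. The score difference kept its sign and threshold with the merged peak lists but shrank to −0.0678 and −0.0706. With the pixel value, another measure whose size cannot be set beside the score, the difference was −0.0849, and the cause was not tested. Within span classes the score difference was 0.0409. Both settings were chosen after seeing the data. The planned overlap rule by which a peak covers part of a region, or the region part of a peak, changes nothing because each peak lies inside its region, and it was not run. The promoter and gene-list alternatives were not run, for lack of a gene table in hg19 among those used here. Depth limits the peak comparisons in an unknown way, as the lists carry no read counts.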

Other observations

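The tests of region width, loops per anchor and wide domains had their expectation written before the result; the deciding bounds for the sides of loops and for chromosomes were reworded after it, and the side test over 200 kb was added after it. Narrow H3K27ac regions behaved apart from wide ones. Of the shared regions, 22023 (31.7%) were at most 250 bp wide, 16840 (24.3%) were over 250 and up to 1000 bp and 30520 (44.0%) were over 1000 bp. The narrow ones lay at a loop anchor in 13.4% of cases against 12.7% ± 0.317 for moved loops, a fold of 1.06 (1.01 to 1.11; one-sided permutation p 0.00899), and with local shifts the fold was 1.01 (0.963 to 1.053; one-sided permutation p 0.364). Regions of the middle width had a fold of 1.48 (1.42 to 1.56), or 1.31 with local shifts, and those over 1000 bp had 1.37 (1.33 to 1.42), or 1.22. The expectation that narrow regions would exceed regions over 1000 bp in this fold was not met. A candidate explanation is that many calls at the shortest width are background that recurs in all 4 libraries, which was not tested further.

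Anchors of several loops held H3K27ac more often than anchors of 1 loop. The share was 48.8% (exact interval 47.9% to 49.8%) for 1 loop, 54.7% (52.7% to 56.6%) for 2 and 55.6% (51.8% to 59.3%) for 3 or more. The odds ratio of 3 or more against 1 was 1.31 (Fisher's exact p 0.000580, adjusted 0.00250 over 5 tests). Wide domains also met anchors more often than chance. Of the 500 domains with the most covered bases, 56.8% touched an anchor against 42.0% ± 2.16 for moved loops, a fold of 1.35 (1.22 to 1.50), with an adjusted permutation p of 0.00250. The other domains had a fold of 1.23 (1.21 to 1.26). With local shifts the folds were 1.22 (1.13 to 1.34) and 1.13 (1.11 to 1.152), and the difference between these folds was not tested. Of the 3 leading domains, on chromosomes 16 and 11, 2 touched no anchor.

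The expectation that H3K27ac would be denser inside loops was not met. The first 100 kb beside anchors of the 5167 loops of at least 240 kb were compared. The inside minus outside difference was −0.112 ± 0.382 percentage points (mean and SD over 22 autosomes, each counted equally). The inside was higher on 11 of 22 (sign-flip permutation p 0.192, adjusted 0.192). Pooled over loops, coverage was 2.84% inside and 2.87% outside. Over 200 kb beside the 2598 loops of at least 440 kb, the outside was denser in 10 of 10 windows. There the difference, again a mean over autosomes, was −0.272 ± 0.474 percentage points, with the outside higher on 16 of 22 autosomes (sign-flip permutation p 0.00842, adjusted 0.0140). Pooled over loops, coverage there was 2.48% inside and 2.66% outside, a smaller difference. Loop density did not clearly follow H3K27ac density between chromosomes. Chromosome 20 had the most loops, at 4.64 per Mb, and chromosome 4 the fewest, at 2.22 per Mb, while shared regions ran from 16.5 per Mb on chromosome 4 to 41.6 per Mb on chromosome 19. Over the 22 autosomes Pearson's r was 0.300 (permutation p 0.175, adjusted 0.192) and Spearman's rho 0.361 (permutation p 0.101). Without chromosomes 17 and 19, the farthest from the median in H3K27ac density, r was 0.296. The data leave a weak relation possible.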
